A study of Drosophila melanogaster with 4 samples.

How the data were processed

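The series comprised ChIP-seq of H3K4me2 in wild-type Oregon-R embryos of Drosophila melanogaster aged 14 to 16 h, with 2 ChIP libraries and 2 input libraries. Per the labels' protocols, embryos were fixed with formaldehyde, chromatin was precleared and incubated with the antibody, immune complexes were collected on beads and washed, and DNA was released by RNase A and proteinase K treatment and extracted with phenol-chloroform. The labels name 1 input for each ChIP replicate.

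The authors deposited 3 lists of regions of significant enrichment, 1 for each ChIP replicate and 1 for the replicate set, in GFF version 3. Per the file headers, the coordinates are those of FlyBase release 5, and the lengths of the sequences were taken from the same headers. The deposited score of each region was positive in all lists and at most 3.78. Its scale, and how the authors normalized the ChIP to the input, are not given in the sources used here. The aligner, the region caller, its threshold, the treatment of reads that align to several places and the read depth are likewise not given. How the authors combined the replicates into the third list is not given either, and that list is reported as the authors' combined value without an SD. Scores were used to rank and describe regions within a list. They were also compared between the replicate lists and averaged over them, on the authors' unstated scale. Region widths were at least 1302 bp and 1305 bp in the replicate lists and at least 1001 bp in the combined list, so shorter enrichments are not represented.

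Positions are 1-based and inclusive. The gene table at hand was on release 6 of the genome, a different build from the lists, and no coordinates were converted. Regions were therefore not assigned to genes, and the planned measurements of promoter share, of marking over 19 fixed gene lists and of domain width at promoters were not run. The regions described individually are, by a rule fixed before the data were examined, the 10 widest and the 10 highest-scoring of the combined list. The strongest unshared regions, the longest empty stretches and the regions that differ most between replicates were chosen after their values were seen.

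The deposited lists were analysed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A region counted as shared when it had at least 1 bp in common with a region of the other list. Chance overlap came from 1000 random placements of each region on its own sequence, keeping its width, with no allowance for unalignable sequence. Scores were compared over regions that overlapped exactly 1 region of the other list in both directions. The interval of their correlation came from 1000 bootstrap samples of 1-Mb blocks. Coverage is the share of a sequence's bases within regions, given as mean ± SD of the 2 replicate lists. Shares of regions carry Wilson 95% intervals, which cover counting error only. X was compared with the arms 2L, 2R, 3L and 3R by the difference in median score, with 100000 permutations of the chromosome label over 1-Mb blocks. Chromosome 4 was compared with non-overlapping runs of the same number of consecutive autosomal regions. The windows next to the centromere were compared with the others by an exact permutation test over all choices of 1 window per arm, added after the data were seen. The proximal end was taken as the high-coordinate end of 2L, 3L and X and the low-coordinate end of 2R and 3R.

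The overlap and block tests were tested on simulated data. With 5049 regions of replicate 1 and true shares of 0%, 30% and 90%, the overlap found was 27.8%, 49.6% and 92.7% where 27.2%, 49.0% and 92.7% were expected. The expected values used the same random placement as the simulated lists. They check the counting only, not whether random placement is a fair measure of chance. With scores of 4919 regions of replicate 1 permuted individually, which removes any likeness of neighbouring scores, the X block permutation test called 1 of 40 simulations without a shift and 25 of 40 with a shift of 0.12 added to X, with a mean estimate of 0.12.

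The replicate lists differ in region number, extent and score and were treated as 2 samples. Alternatives fixed in advance were the upper 50% of scores, other overlap criteria, merging of regions less than 500 bp apart, restriction to 2L, 2R, 3L, 3R, 4 and X, equal numbers of top-scoring regions, counts per Mb in place of coverage, and each replicate alone. The use of the combined list as an alternative was added later. The comparisons of scores between chromosomes and of the heterochromatic sequences, with their alternatives, were added after the data were seen.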

Results

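H3K4me2, the dimethylated form of lysine 4 of histone H3, is found at promoters and enhancers of active or poised genes. Its distribution was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in embryos of the wild-type Oregon-R strain of Drosophila melanogaster, aged 14 to 16 h, the period of late embryogenesis in which nervous system, muscle and cuticle differentiate. The series held 4 libraries, made up of 2 ChIP libraries precipitated with an H3K4me2 antibody and 2 libraries of input DNA, 1 for each ChIP. The data were the authors' lists of significantly enriched regions on FlyBase release 5, with 1 list for each ChIP replicate and 1 combined list for the replicate set. The input libraries entered through the authors' calls and had no list of their own. The number of sequenced reads behind each list was not given in the sources used here, so the depth is unknown. The labels do not say whether the replicates came from separate embryo collections, and the spread between them may be technical.

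H3K4me2-enriched regions numbered 5049 in replicate 1 and 5063 in replicate 2 (mean 5056 ± 9.9 SD, n = 2). They covered 18.8 Mb and 18.1 Mb of sequence (mean 18.4 ± 0.47 Mb SD, n = 2). The median region was 3105 bp wide in replicate 1 and 3034 bp in replicate 2, and the widest reached 19562 bp and 18671 bp. Regions of high score were wide. Those in the highest score quartile had a median width of 4364.5 bp in replicate 1 and 4234 bp in replicate 2, against 2095 bp and 2081 bp in the lowest quartile. Across regions within a list, width and score correlated with a Spearman rho of 0.69 in replicate 1 and 0.70 in replicate 2. Regions are not independent replicates, so no p-value is attached to these values. The score is the authors' own value per region, and its scale was not stated.

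The scores had 2 maxima in each list. In both replicates the lower maximum lay between 0.5 and 0.75, with 503 regions in replicate 1 and 626 in replicate 2. The number of regions then fell to 315 and 399 between scores of 1 and 1.25. It rose again to 629 regions between 2.25 and 2.5 in replicate 1 and to 705 regions between 2 and 2.25 in replicate 2.

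**Figure D1:**
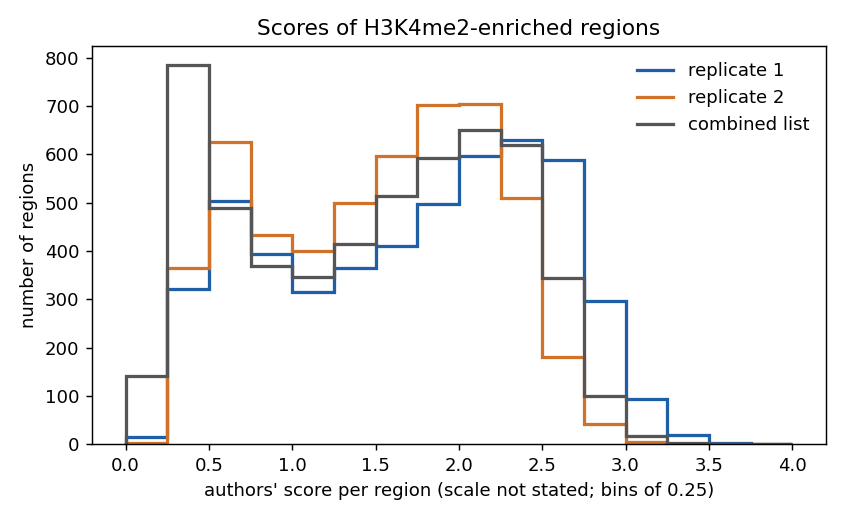
Number of H3K4me2-enriched regions (vertical axis) by the authors' score in bins of 0.25 (horizontal axis), for replicate 1, replicate 2 and the combined list. Each list has a low and a high maximum with fewest regions between them at scores of 1 to 1.25.

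The comparison that the design implies is between the replicates, and nearly all regions recurred. Of the 5049 regions of replicate 1, 4838 (95.8%, Wilson 95% interval 95.2 to 96.3) had at least 1 bp in common with a region of replicate 2. In the other direction, 4926 of 5063 regions (97.3%, interval 96.8 to 97.7) were shared. These intervals cover counting error only. Random placement of the same regions on their own chromosomes gave 26.7% and 26.9% on average and at most 28.8% and 29.1%. The observed overlap exceeded all 1000 placements in both directions (one-sided permutation test, p = 0.001, the smallest that 1000 placements can give). The lists had 17.6 Mb in common, a base-pair Jaccard index of 0.91.

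Regions found in only 1 replicate were weak and narrow. The 211 regions of replicate 1 without a partner had a median score of 0.49, against 1.91 for shared regions, and a median width of 1576 bp against 3218.5 bp. The 137 regions of replicate 2 without a partner had a median score of 0.48 against 1.62 and a median width of 1549 bp against 3089 bp. The lowest score quartile held 203 of the 211 and 134 of the 137, and 0 in either replicate had a score above the median of its list. The strongest region confined to replicate 1 lay on the unplaced sequence U (9619511 to 9620815, score 1.60), followed by a region near the end of chromosome 4 (1311625 to 1313691, score 1.56) and one on X (10500417 to 10502190, score 1.42). The strongest confined to replicate 2 were on U (7536063 to 7538000, score 1.37), on 2R (1258587 to 1260115, score 1.07) and on 3R (16974930 to 16976327, score 1.05).

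Scores and extents of shared regions were closely related between replicates. Over the 4628 regions matched one to one, the Spearman rho of scores was 0.98 (95% interval 0.98 to 0.98 from a bootstrap of 1-Mb blocks) and Pearson's r was 0.98. The rho of widths was 0.97, and both ends lay within 250 bp of each other for 3723 regions (80.4%). Scores were higher in replicate 1 for 4201 of the matched regions (90.8%), with a median difference of 0.27 (SD over regions 0.18). The scale of the scores is not stated, and this shift is given as a value only. A small set of regions departed from the common trend. On proximal 2L, 4 regions between 21463511 and 21481148 scored 1.81 to 2.21 in replicate 1 and 0.89 to 1.46 in replicate 2. On U, the region from 5536825 to 5539643 scored 2.37 in replicate 1 and 3.23 in replicate 2, the highest score of that list. On X, the region from 13071314 to 13073464 scored 1.72 in replicate 1 and 0.56 in replicate 2.

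**Figure D2:**
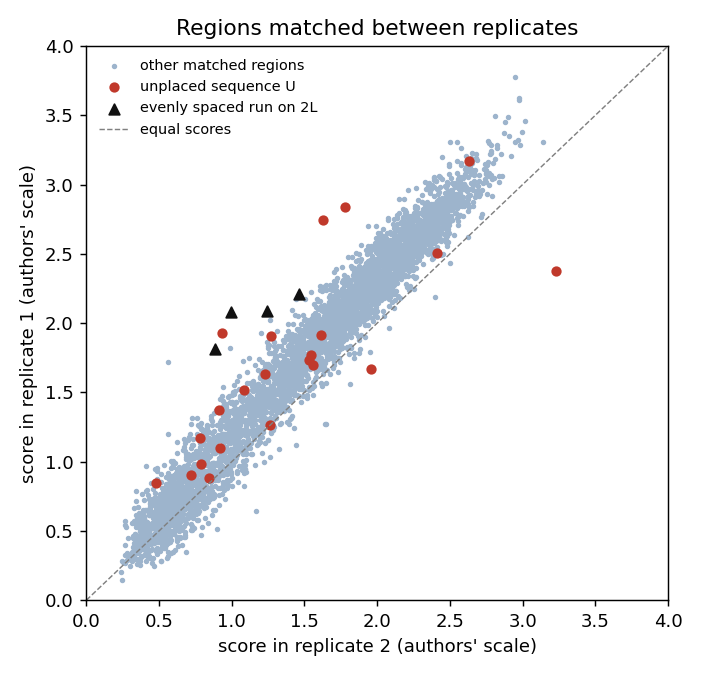
Score in replicate 1 (vertical axis) against score in replicate 2 (horizontal axis) for the 4628 regions matched one to one, both on the authors' scale; the dashed line marks equal scores. Most points lie above the line, and several regions of the unplaced sequence U and the 4 evenly spaced regions of proximal 2L lie away from the rest.

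The combined list held 5383 regions covering 20.0 Mb, both the authors' values for the replicate set. Of these, 4766 (88.5%, Wilson 95% interval 87.7 to 89.4) overlapped regions of both replicates and made up 95.2% of its covered sequence. A further 198 overlapped replicate 1 alone and 126 replicate 2 alone, with median scores of 0.33 and 0.33. The remaining 293 regions (5.44%, interval 4.87 to 6.08) overlapped neither replicate. Their median score was 0.35 and their median width 1251 bp, and 170 of them were narrower than any region of the replicate lists. Of these 293, the 4 of highest score lay on U, led by the region from 7531103 to 7533103 with a score of 2.53. Among the next were regions of proximal 2L at 21539832 to 21541674 (score 1.64) and 21458315 to 21460472 (score 1.59). Nearly every replicate region was retained, with 9 of replicate 1 and 5 of replicate 2 absent from the combined list.

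Enriched sequence was spread over all chromosome arms. Regions covered 17.5% ± 0.34 of 2R, 15.5% ± 0.40 of 3R, 14.4% ± 0.23 of 3L and 13.6% ± 0.37 of 2L (mean ± SD, n = 2). The X, at 15.3% ± 0.54, lay within the range of the autosomal arms. Its covered share was 1.00 ± 0.014 times that of the 4 autosomal arms together. The small chromosome 4, which is largely heterochromatic but carries active genes, had 12.2% ± 0.48 of its sequence covered, 0.80 ± 0.014 times the autosomal arms. Among the upper 50% of scores in each list this ratio was 0.31. The differences of 2R from 2L and of chromosome 4 from the autosomal arms exceeded the spread between replicates. Single windows of 2 Mb on the autosomal arms ranged from 3.77% to 22.9%, and 11 of 46 were covered less than the short chromosome 4. No p-value is given for the covered shares, which rest on 2 lists.

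The assembled heterochromatic sequences had a low share covered by enriched regions. Together, the 6 sequences of 9.28 Mb had 51 regions in replicate 1 and 46 in replicate 2, covering 1.40% ± 0.097 (SD, n = 2) against 15.2% ± 0.34 of the autosomal arms. The covered share was 0.888% ± 0.013 in 3RHet, 0.958% ± 0.13 in 2RHet and 1.54% ± 0.066 in 3LHet. It was higher in the shorter sequences, with 2.86% ± 0.021 in 2LHet, 3.56% ± 0.45 in YHet and 6.55% ± 0.57 in XHet. These shares rest on few regions, with 3 in each replicate in 2LHet and 5 and 4 in XHet. YHet, which comes from the Y chromosome, held 6 regions in replicate 1 and 5 in replicate 2. Relative to the autosomal arms the share was 0.092 ± 0.0044, and 0.041 among the upper 50% of scores in each list. The share of these sequences to which reads could be aligned is unknown, so their low coverage need not mean less H3K4me2.

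**Figure D3:**
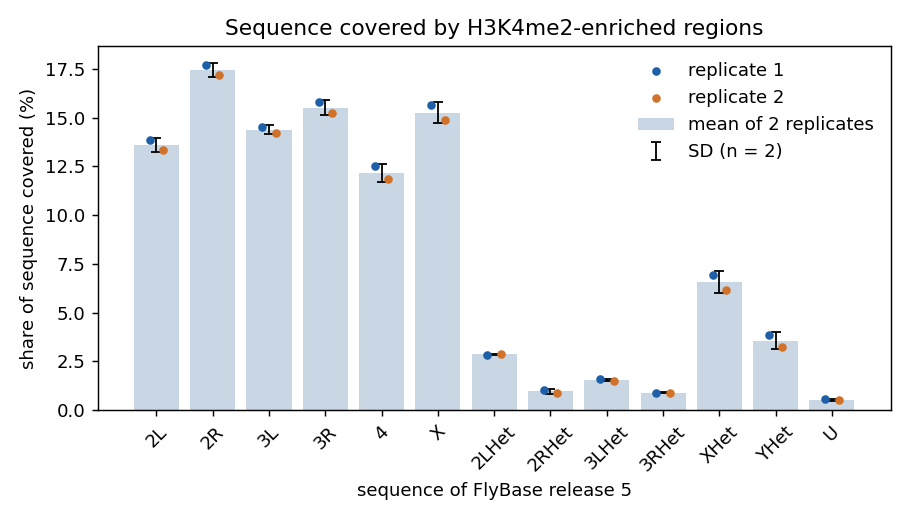
Share of each sequence of FlyBase release 5 covered by H3K4me2-enriched regions (vertical axis, percent); bars are the mean of 2 replicates, error bars the SD and points the replicates. The arms and chromosome 4 lie between 12.2% and 17.5%, and the heterochromatic sequences between 0.888% and 6.55%.

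The window next to the centromere had the lowest coverage of its arm on 4 of the 5 large arms. In windows of 2 Mb counted from the centromeric end, the first window was covered to 8.66% ± 0.44 on 2L, and on 2R to 8.27% ± 0.034, on 3L to 3.77% ± 0.080 and on X to 6.58% ± 0.26 (SD, n = 2). The other windows of these arms averaged 13.8%, 18.4%, 15.2% and 16.2%, and the lowest of them had 9.25%, 15.2%, 10.3% and 11.2%. On 2L the first window lay close to windows 3, 4 and 5 (9.25% ± 0.51, 9.46% ± 0.26 and 9.65% ± 0.18), while window 2 had 15.2% ± 0.56. On 3R the first window was covered to 19.2% ± 0.37, above the average of 15.5% over its other windows. On the 5 large arms and chromosome 4, the longest stretches between regions of the combined list were 348 kb on 2L (16910864 to 17258458), 344 kb on proximal X (21501804 to 21845698) and 306 kb on 2L (14690002 to 14995690), and no region of either replicate lay within them. Over the 5 arms, 3R included, the first window differed from the mean of the other windows by -6.61 percentage points in replicate 1 and -6.38 in replicate 2. Among all 188760 choices of 1 window per arm, the two-sided exact permutation p was 0.00062 and 0.000609. This test was chosen after the windows were seen, is not adjusted, and treats the windows of an arm as exchangeable. Coverage was taken over the full window length, and the share of each window to which reads could be aligned is unknown. Lower coverage next to the centromere therefore need not mean less H3K4me2.

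**Figure D4:**
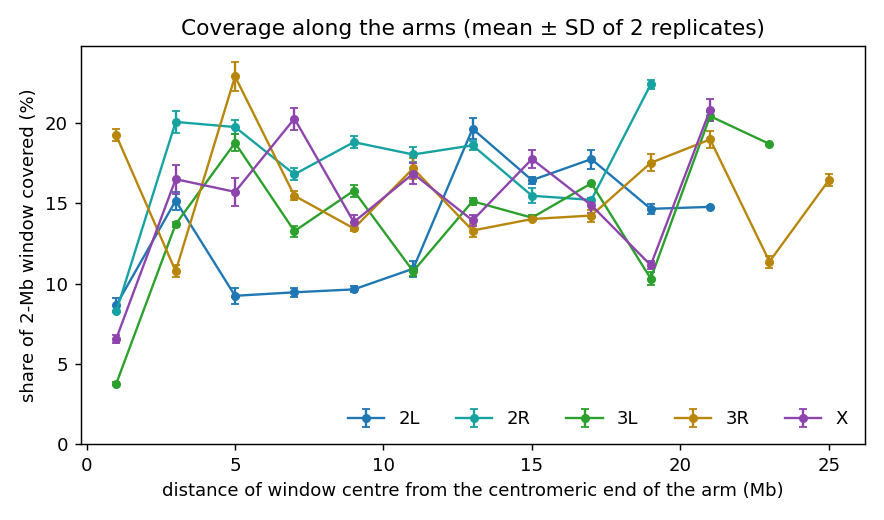
Share of each 2-Mb window covered (vertical axis, percent) against the distance of the window's centre from the centromeric end of the arm (horizontal axis, Mb), as mean ± SD of 2 replicates; the remainder shorter than 2 Mb at the telomeric end is left out. The first window is the lowest of its arm on 2L, 2R, 3L and X but not on 3R, where it reaches 19.2%.

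The scores of regions on X and chromosome 4 were compared with those on the autosomal arms. On the X, the median score was 1.97 against 1.85 on the 4 autosomal arms in replicate 1 and 1.72 against 1.59 in replicate 2, a difference of 0.12 and 0.13. Regions on X were also wider, and among regions of the same width the difference was smaller, 0.083 in replicate 1 and 0.068 in replicate 2 (permutation p = 1e-05 in each, the smallest that 100000 resamples can give). The X had the highest median of the 5 large arms in both replicates. Of the 100 highest scores, the X held 39 in replicate 1 and 41 in replicate 2, although only 17.7% and 17.5% of regions were on the X. Exchanging the chromosome label over 121 blocks of 1 Mb gave a two-sided permutation p of 0.0186 in replicate 1 and 0.00219 in replicate 2. After Benjamini-Hochberg adjustment over 4 permutation tests (X and chromosome 4 in 2 replicates), these were 0.0346 and 0.00876. The permutations for X treat blocks of the genome as exchangeable and measure the spread among blocks, not between replicates or chromosomes. The replicate lists share nearly all regions, so their p-values are not independent of each other. In the combined list the difference was 0.085 and did not pass (permutation p = 0.0675). The score comparisons of X and chromosome 4 were chosen after the data were examined.

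Chromosome 4 had lower scores than the autosomal arms at the upper percentiles. Its 53 regions in replicate 1 had a median of 1.49 and a 90th percentile of 2.07, against 1.85 and 2.67 on the autosomal arms. Its 52 regions in replicate 2 had a median of 1.22 and a 90th percentile of 1.68, against 1.59 and 2.33. Set against 74 and 76 runs of as many consecutive autosomal regions, the deficit of the median gave a two-sided permutation p of 0.0667 in replicate 1 and 0.026 in replicate 2 (adjusted 0.0667 and 0.0346), so that it passed in replicate 2 and not in replicate 1. At the 90th percentile, chosen after the medians were seen, the difference was -0.60 and -0.65, lower than in every one of these autosomal runs (permutation p = 0.0133 and 0.013, the smallest they can give, not adjusted). Among regions of the same width, the difference in medians was -0.30 on average over the replicates and passed (permutation p = 0.0133, the larger of the replicates). In the combined list it was -0.30 and did not pass (permutation p = 0.123). At the 10th percentile, chromosome 4 differed from the autosomal arms by -0.061 in replicate 1 and 0.0027 in replicate 2.

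**Figure D5:**
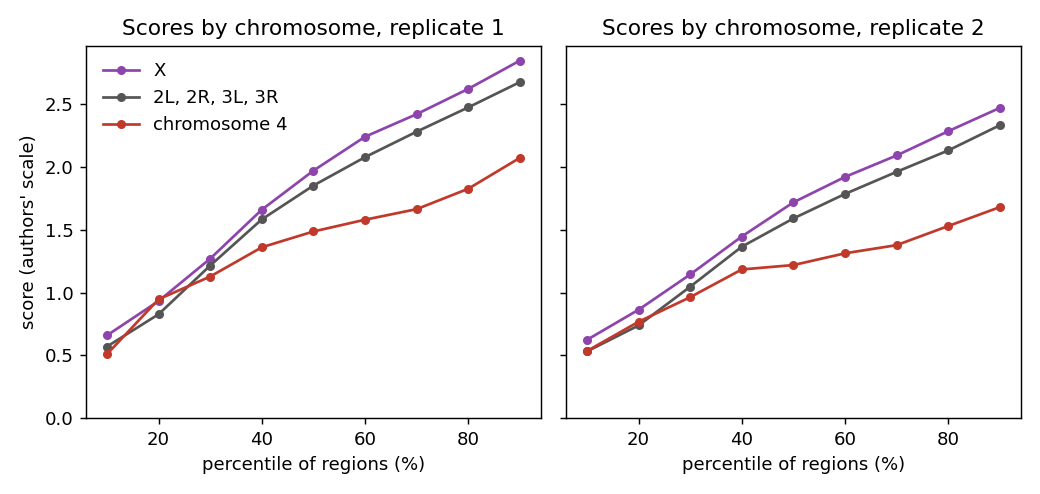
Score (vertical axis, authors' scale) at percentiles of regions from 10 to 90 (horizontal axis) on X, on the 4 autosomal arms and on chromosome 4, in replicate 1 and replicate 2. The X lies above the autosomal arms throughout, and chromosome 4 falls below them at the upper percentiles, reaching 2.07 and 1.68 at the 90th.

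The individual regions are given by position, since no gene annotation of release 5 was used here and gene, exon, intron and UTR assignments were not made. All 10 widest and all 10 highest-scoring regions of the combined list scored higher in replicate 1. The SDs of their scores therefore include the general shift of scores between replicates. The widest region of the combined list, 18765 bp, lay on 2L from 4964807 to 4983571 and scored 2.80 in replicate 1 and 2.43 in replicate 2 (mean 2.62 ± 0.27 SD, n = 2). It was followed by an 18345-bp region on 2R from 8054354 to 8072698 (mean score 2.32 ± 0.31) and a 17366-bp region on X from 508508 to 525873 (2.61 ± 0.19). The next were a 16937-bp region on 2L from 11986229 to 12003165 (2.64 ± 0.26) and a 16702-bp region on X from 1961840 to 1978541 (2.25 ± 0.21). These 5 were each called as a single region in both replicates, with a width SD of at most 211 bp (n = 2). Other long domains, on 2L from 4450944 to 4466677 (15734 bp, mean score 2.57 ± 0.27) and on X from 16673113 to 16688776 (15664 bp, 2.32 ± 0.30), were also single regions in both.

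The remaining 3 of the 10 widest were divided in at least 1 replicate. The domain on 2L from 19569568 to 19586258 (16691 bp) was a single region of 19562 bp in replicate 1 and was split into 2 in replicate 2. The domain on 3L from 627770 to 644359 (16590 bp) was split into 3 and 2 regions and had the lowest combined score of the 10, 1.28. The domain on X from 1352547 to 1368370 (15824 bp) was split into 2 and 3 regions and had the highest, 2.72.

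The regions of highest score were of moderate width, between 3897 and 6845 bp, and 7 of the 10 lay on X. The highest in the combined list was X 20261563 to 20267881, with a combined score of 3.29 and scores of 3.78 and 2.95 in the replicates (mean 3.36 ± 0.59 SD, n = 2). X 14130094 to 14134119 had a mean score of 3.29 ± 0.45, X 17753150 to 17757046 of 3.24 ± 0.31 and X 19371598 to 19377531 of 3.30 ± 0.46. X 1932843 to 1937277, X 2501194 to 2505323 and X 6180283 to 6187127 had mean scores of 3.16 ± 0.41, 3.13 ± 0.22 and 3.13 ± 0.25. The autosomal members were 2L 9965066 to 9969453 (3.22 ± 0.12), 2R 19735978 to 19741030 (3.20 ± 0.42) and 2R 4786229 to 4791099 (3.19 ± 0.27). All 10 were single regions in both replicates and ranked among the first 19 by score in replicate 1 and the first 16 in replicate 2. None of the 10 widest was among them.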

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

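All tests of the spread of scores given here were chosen after the result on U was seen, and the one on the heterochromatic sequences replaced a test on U itself when the value of 1 YHet region was already known. The unplaced sequence U (10.0 Mb), which the comparison of chromosome arms leaves out, held 26 regions in replicate 1, 23 in replicate 2 and 38 in the combined list, a signal outside the sequences compared. These covered 0.529% ± 0.042 of U (SD, n = 2), and 11 of the 38 overlapped neither replicate. No region was listed on the 29.0 Mb of Uextra.

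Around the line through all matched regions, the residual SD was 0.47 over 22 regions of U and 0.15 over 4562 regions of the arms and chromosome 4, a ratio of 3.13 (one-sided permutation p = 0.0001, the smallest that 10000 resamples can give). Much of this rests on 4 of the 22 regions with residuals above 0.75 in size, which 3 of the 4562 reached, and without these regions on either side the ratio was 1.63. A candidate explanation is uneven placement of reads in repeat-rich sequence, which would also widen the spread on the assembled heterochromatic sequences. There the ratio was 1.33 over 44 regions (one-sided permutation p = 0.0177), but without the YHet region known beforehand it was 1.17 and did not pass (permutation p = 0.088), so the explanation stays open. Copy number was not tested, and no biological explanation was tested because both replicates are of one stage and strain.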

How the results depend on the processing

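The alternatives for the heterochromatic sequences and for scores on X and chromosome 4, and those using the combined list, were chosen after the results were seen. Of 59 alternatives, 42 left the result in place (tests on the same side of the threshold, region counts within 1.5 times, other values within their spread), 13 moved a value further than this, 1 left a difference short of a threshold it had passed and 3 took a difference past a threshold it had missed. Some of these outcomes were fixed by construction. With 2 replicates, either alone lies within their SD of the mean, so leaving 1 out could not move covered sequence or a coverage ratio. In the score comparisons the main p was the larger of the replicates, so a replicate alone gave no new test. The X coverage ratio, which is close to 1, fell on either side of it. Overlap between replicates passed its permutation test under all 6 alternatives in both directions, at 94.1% to 98.2% of regions. Merging regions less than 500 bp apart left 4688 regions per replicate and restriction to the arms and chromosome 4 left 4983, both beyond the SD between replicates. Restricting each list to the upper 50% of scores changed, by construction, the mean number of regions to 2527.5 and the covered sequence to 11.4 Mb. In the same subset, rho between replicates was 0.90, 87.4% of combined regions were in both replicates, and the covered share relative to the autosomal arms was 1.09 for X, 0.31 for chromosome 4 and 0.041 for the heterochromatic sequences. Pairing each region with its best overlapping partner gave a rho of 0.97. With either replicate alone, 90.9% to 92.2% of combined regions were recovered. Counted per Mb instead of by coverage, the ratios were 0.95 for X, 0.93 for chromosome 4 and 0.12 for the heterochromatic sequences. In the combined list, the score difference was 0.085 for X (permutation p = 0.0675) and -0.30 for chromosome 4 (permutation p = 0.123), and neither passed, which for X is a change; the cause was not tested. The other alternatives for X gave 0.075 to 0.13 and passed. For chromosome 4, the difference in medians (mean -0.368) did not pass in both replicates. It was -0.371 in replicate 2 alone, which passed, and -0.365 in replicate 1 alone, which did not. The difference was -0.627 at the 90th percentile and -0.304 among regions of the same width, and both passed (permutation p = 0.0133 each, the larger of the replicates); the cause was not tested. No paired analysis was possible because the input libraries have no values of their own here. Promoter share, gene list marking and promoter domain width, and their alternatives, were not run, as no annotation of release 5 was used. Leaving out a replicate gives no value for overlap or rho. Read depth is unknown, so its effect on the number of weak regions could not be assessed.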

Other observations

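The tests on X and on proximal 2L, and the repeat on merged regions, were chosen after the results were seen. Regions of high H3K4me2 score lay closer to their nearest neighbour, of any score, than regions of low score. Regions in the highest score quartile had a median distance of 1936 bp to the nearest other region in replicate 1 and 1879 bp in replicate 2, against 4504 bp and 4609 bp for the lowest quartile. Neighbouring regions also had related scores, with a Spearman rho over consecutive regions of 0.14 in replicate 1 and 0.15 in replicate 2 (mean 0.142). Permuting scores within chromosomes gave a two-sided permutation p of 0.0001 for each value, the smallest that 10000 resamples can give. The hypothesis that low-scoring regions are mainly flanks of stronger domains had been taken to predict shorter distances for the lowest quartile. The difference found, 2649 bp (mean of the replicates, lowest minus highest quartile), had the opposite sign. High-scoring regions were also wider, and the distances were not compared at equal width. The permutation does not separate score from width. A weak flank beside a strong region would also shorten the distance of both, so the difference cannot decide on the hypothesis. After merging regions less than 500 bp apart, the difference was 2783.5 bp and 3293.5 bp, so division of strong domains by gaps shorter than 500 bp is not needed for it. Division by longer gaps was not tested.

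Regions on X had higher scores in both replicates, while in the combined list the difference of 0.085 did not pass (permutation p = 0.0675). The median X region was wider, 3238.5 bp against 3112 bp in replicate 1 and 3208 bp against 3034 bp in replicate 2. Among regions of the same width a difference of 0.075 remained (mean of the replicates). Its permutation p was 1e-05 in each, the smallest that 100000 resamples can give. Width and score both come from the authors' calls, so this comparison does not show whether width is a cause of score. The excess on X was not confined to very strong regions. At the 10th percentile X exceeded the autosomal arms by 0.090 (mean of the replicates, permutation p = 0.0011 and 0.0002). X also had fewer regions per Mb, 39.8 and 39.6 in the replicates against 41.7 and 42.0 on the autosomal arms. Whether a lower number of weak regions on X raised its percentiles was not tested. One constant offset of all X scores, as a normalization step might add, cannot be told apart from a difference that grows with score: the difference at the 90th percentile exceeded that at the 10th by 0.064 on average, with bootstrap intervals from -0.018 to 0.17 and from -0.024 to 0.12. Males carry a single X, and both the sex of the embryos and the input signal on X are unknown here, so a biological origin stays an open hypothesis.

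On proximal 2L, the combined list had 5 evenly spaced consecutive regions from 21458315 to 21481143 with a mean start-to-start distance of 5044 bp and a coefficient of variation of 2.49%, the lowest of 5270 such runs, the next elsewhere being 5.83%. The 4 of them present in both replicates exceeded the general trend between replicates by 0.70 on average, against at most 0.32 in 4537 other runs of 4. The even spacing is what a tandem repeat would give, but it was part of the pattern noticed and is no separate test of that explanation. Copies of one sequence can share reads, depending on the treatment of reads that align to several places, which is not given. The 4 values may therefore be a single measurement. A departure as large as this mean was reached by 2 of 4558 other single regions. The member not noticed by its departure had a residual of 0.50, which 11 of these 4558 reached. Because the other 3 were noticed by this departure and the 4 may be a single measurement, the comparison cannot decide. The departure cannot be told apart from the scatter around the general shift between replicates. The tandem array of replication-dependent histone genes is known to lie on proximal 2L, but whether it falls at these positions was not checked.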
